A study of Caenorhabditis elegans with 4 samples.

How the data were processed

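ChIP-seq libraries of whole L4 larvae of a strain with an integrated ces-1 transgene tagged with GFP were analysed as 1 group of 4 biological replicates, numbered as in the labels. Replicates 1 and 2 have a stated fragment size range of 150 to 350 bp, and replicates 3 and 4 were fragmented by sonication with a microtip, per the labels. Replicates are separate samples of one strain by the labels.

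Peak lists were used as deposited by the authors, in the 10-column narrowPeak layout. Per the file records, each library's list, a pooled list from all 4 alignments and an IDR-thresholded list derived from the pooled and single lists were deposited for ce11 and for ce10, and every library was compared with the same single control. The peak caller, its settings, the IDR threshold and the aligner are not given in the sources used here, and the control library was not used here. Each region has a signal score deposited by the authors, whose scale is not stated. It was used to describe, rank or filter regions within one list, was summed over windows of one list for the locus ranks, and was correlated between libraries. The deposited −log10 q-value reaches its maximum at 81.5% of the IDR peaks and was not used for ranking. The q-value column was used in no test. Each library's list stops at exactly 30000 regions, and whether its weaker regions pass a threshold of significance was not examined. Most regions of a list have one fixed width, 316, 336, 356 and 370 bp in replicates 1 to 4 of ce11. Read counts are unknown, so no depth, counting interval or normalised coverage was computed. In replicate 1, 6 regions repeat the coordinates of another and were kept. No 2 libraries shared a region with identical coordinates. In the whole-series lists, 0 measurement columns were left out.

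Coordinates are those of ce11 (WBcel235), 1-based. The last base of every chromosome's pooled regions lay within the WBcel235 chromosome lengths, and on the mitochondrial chromosome it equalled the length, 13794. Genes came from Ensembl release 115. The ce10 lists were used only for counts, with no conversion of coordinates. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots used matplotlib 3.10.9.

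The promoter window ran from 1000 bp upstream to 200 bp downstream of the 5′ end of any transcript of any gene type. A summit was assigned to the first that applied of coding exon, 5′ UTR, 3′ UTR, exon of a non-coding gene other than piRNA genes, intron of a protein-coding gene and intergenic. The promoter share was compared with 1000 random placements of the summits within their chromosomes and, with Fisher's exact test (two-sided), with the 24333 pooled regions that overlap no IDR peak. E-boxes, the 10 distinct CANNTG sequences, were searched on both strands within 50 bp of each summit. Background windows came from the same 24333 regions, 5 per peak, matched on GC content in steps of 0.05 and on promoter class; 26 background windows fell short of that number. A gene list was tested by whether its genes had an IDR summit in the promoter window, among the 16324 genes with any summit of the pooled list there, of which 979 had an IDR peak. Chromosome shares were compared with the pooled list. Odds ratios have 0.5 added to each cell and 95% confidence intervals by Woolf's method. Benjamini-Hochberg adjustment was made over 23 gene lists, 10 E-boxes and 7 chromosomes, and the threshold was 0.05. Peaks and genes are not biological replicates: these p-values compare sets within lists made from the 4 libraries, and values per library with the SD over 4 show the spread between replicates.

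Agreement between libraries was measured on the 2000 regions of highest signal of each. The locus check ranked the 40 kb window centred on ces-1 among 2503 consecutive windows by number of regions and by summed signal. Named genes were chosen by a rule set before the data were examined: ces-1 first, every gene of the list of CES-1 function and cell death (those without a peak as a count with at most 6 names, which the members named for their weaker regions exceed), the 25 protein-coding genes with the strongest promoter peak found in all 4 libraries (the nearest 5′ end where several genes share a window), and up to 4 members with the strongest peaks of each of the 23 lists. The lists, by gene symbol, and their test, the promoter, E-box and chromosome comparisons and the agreement between libraries were also set then. Annotation classes of the summits, comparisons of the strongest with the weakest regions of each library, list tests in single libraries and the unc-42 locus were added after the data were seen. The strongest and weakest regions of a library were not matched on GC content or promoter class.

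Motif, gene list and placement steps were tested on simulated data. With nothing planted, 0 of 10 E-boxes were called and CAGGTG had an odds ratio of 0.69. With CAGGTG planted in 2% of 1000 windows, the odds ratio was 1.58 and was not called (adjusted p = 0.22, Fisher's exact test), and planted in 10% it was 5.71. With 900 bound genes drawn at random among 16324, 1 list of 1150 tested in 50 draws was called, and a 4-fold weight on the ribosomal list was called in 36 of 50 draws. Uniform points gave a placement p of 0.562. A count set at 60% of points in promoters, with no points drawn for it, gave 0.005, the smallest value the draws of this check can give. The E-box check was run without matching on GC content and promoter class, so it does not test that step.

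The alternatives were ce10 in place of ce11, the upper part of the IDR list by signal (517 peaks), 1000 and 5000 strongest regions per library, an overlap of at least 50% of the shorter region, Pearson's r of log2 signal, promoter windows of 500 and 100 bp or 2000 and 500 bp, motif windows of 100 bp, flanking windows 300 to 400 bp from the summits, ACAGGTG in place of CAGGTG, all annotated genes as background, peaks found in all 4 libraries, a 20 kb locus window and each library left out in turn. Restriction to nuclear peaks, to protein-coding genes, to peaks outside promoter windows and other backgrounds for X were added after the data were seen, as were the comparisons of gene kinds without piRNA genes, and also without pseudogenes, protein-coding genes as the background of the gene lists, the nuclear peaks of the upper part of the list for X, the count of measures that separate pairs of libraries, and the palindrome on chromosomes II, IV and X alone.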

Results

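Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in whole *Caenorhabditis elegans* at the L4 stage, the last larval stage, in a strain carrying a GFP-tagged copy of ces-1. CES-1 is a zinc finger factor of the Snail family, known for blocking the programmed death of the sister cells of a pair of pharyngeal neurons. The series holds 1 group of 4 biological replicates and no second condition, so the comparisons are between the libraries, and between the submitters' reproducible peaks and weaker regions of the same lists. The labels give a fragment size range for replicates 1 and 2 and sonication with a microtip for replicates 3 and 4; whether other steps differed is not stated. Each library is given as its 30000 strongest regions. A pooled list from all 4 libraries holds 25493 regions, and 1033 peaks pass the irreproducible discovery rate (IDR) step in the ce11 genome build. The number of reads behind each library is unknown.

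The first question was whether the tagged gene itself stands out. It did not. The ces-1 gene lies on chromosome I from 8633897 to 8636169 on the forward strand. No IDR peak lay in the 40 kb window centred on it, from 8615034 to 8655033, and the nearest one, at 8657966 to 8658309, was in the promoter window of the neuropeptide gene flp-22. Only replicate 1 had a region with its summit in the ces-1 promoter window, from 8633541 to 8633856, with a signal of 2.6 and a rank of 26152 among 30000. Replicates 2, 3 and 4 had none. By summed signal, the 40 kb window lay at the 55.9th percentile of 2503 windows of the genome in replicate 1, at the 39.4th in replicate 2, at the 7.4th in replicate 3 and at the 15th in replicate 4, a mean of 29.4 ± 22.3 (SD, n = 4). The position of the transgene in the genome is not given in the sources used here, and this locus tests neither the presence nor the level of the tagged protein.

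The strongest nuclear locus was unc-42 in all 4 libraries. unc-42 encodes a paired-like homeodomain factor that sets the identity of command interneurons and other neurons. The gene lies on chromosome V from 9764534 to 9769391 on the reverse strand. The strongest nuclear peak, from 9765607 to 9765976 with a pooled signal of 723.2, had its summit in an unc-42 intron. The next, from 9769397 to 9769814 with a pooled signal of 638.1, had its summit 211 bp upstream of the 5′ end of the gene. Another peak, from 9768857 to 9769259 with a pooled signal of 348.9, lay in the 5′ part of the gene, where a non-coding gene has an exon, and one more, in an intron from 9768057 to 9768247, reached 190.4. The intronic summit region ranked 9 in replicate 1, 4 in replicate 2, 6 in replicate 3 and 10 in replicate 4. Summed over 40 kb, the signal at unc-42 was 714.4 in replicate 1, 799.0 in replicate 2, 319.6 in replicate 3 and 592.7 in replicate 4, where the median window held 57.1, 70.5, 49.0 and 79.7. The locus was singled out after its values were seen; the strongest peak also belongs to the genes chosen by the fixed rule.

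**Figure D1:**
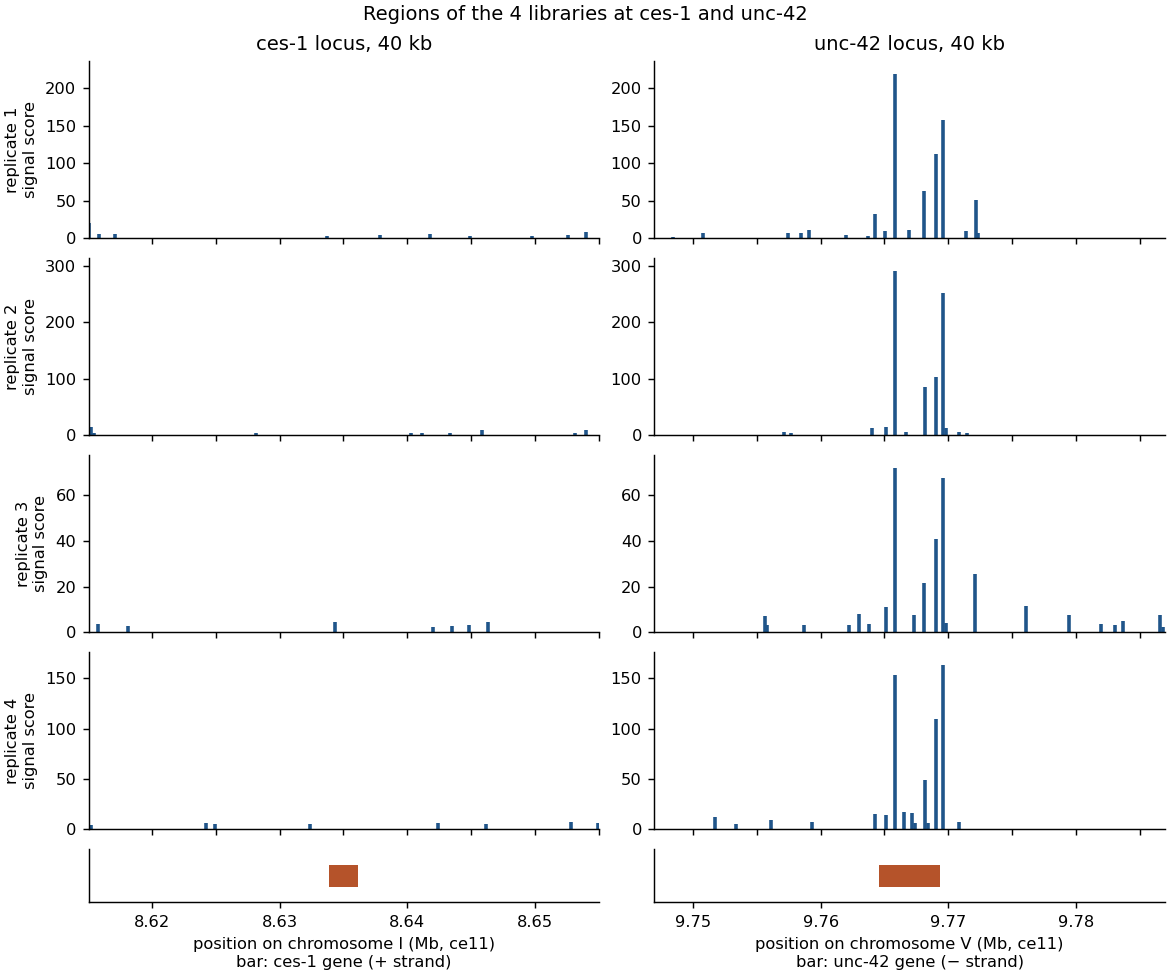
Regions of each library in 40 kb windows centred on ces-1 (left) and unc-42 (right). Each line stands at a region's summit, with the position in Mb of ce11 on the horizontal axis and the deposited signal score on the vertical axis, whose range is shared by both windows of a library but not between libraries; the bar is the gene. The strongest ces-1 window region reached a signal of 20.4 in replicate 1, where the strongest unc-42 region reached 218.3.

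None of the fixed genes of CES-1 function and cell death carried an IDR peak in its promoter window, taken from 1000 bp upstream to 200 bp downstream of any annotated 5′ end. The list holds 25 genes, of which 12 had a region of the pooled list there and so could have been called. Members without a peak include egl-1, the BH3-only cell death activator, ced-9, the worm homologue of BCL-2, ced-3, the executing caspase, ces-2, the bZIP regulator of ces-1, hlh-2 and hlh-3. Among these named members only ced-9 had a region of the pooled list in its promoter window, so the others could not have been called. Weaker regions were present at some members. The 4 members with the strongest pooled regions, named after their values were seen, were ced-5 (pooled signal 36.1), crn-1 (35.5), dnj-11 (32.2) and the kinase gene pig-1 (32.1). In replicates 1 to 4 the strongest region ranked 425, 4110, 24067 and 5849 at ced-5, 1626, 1400, 8276 and 1927 at crn-1, and 6363, 1575, 1505 and 2962 at pig-1. These were not always the same site. The crn-1 region of replicate 4 (3480854 to 3481223) did not overlap the pooled one (3481427 to 3481770). Nor did the pig-1 region of replicate 3 (517938 to 518293) overlap its pooled one (519433 to 519776). At dnj-11 the ranks were 731 in replicate 1, 4091 in replicate 2 and 2286 in replicate 3, with no region in replicate 4. At egl-1 a region was listed in replicate 2 alone, at rank 10967. With 12 genes in the test the odds ratio of this list, 0.63 (95% confidence interval 0.04 to 10.58), bounds neither enrichment nor depletion. With the 2000 strongest regions of each library as the bound set, it was 3.14, 1.85, 0.93 and 1.51 in replicates 1 to 4, and no library passed Fisher's exact test (lowest adjusted p = 0.48).

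Genes of cytosolic ribosomal proteins, chaperones and oxidative phosphorylation carried peaks more often than other genes. A peak was counted for every gene whose promoter window held its summit, so a shared peak counts for each gene. Peaks that lay nearer the 5′ end of another gene include those at rpl-20, rps-19, rps-12, rps-0, hsp-60, cct-1 and cox-6B. Shared peaks include those of rpl-36 and rps-14 and of hsp-110 and rpn-3. In lists that did not pass, mrpl-1 and mrps-24 shared a peak, as did pbs-2 and eif-6. Of 67 cytosolic ribosomal protein genes with a region in the pooled list, 25 (37.3%) had an IDR peak in the promoter window, against 5.87% of other genes, an odds ratio of 9.62 (5.86 to 15.79; adjusted p = 7.1e-13, Fisher's exact test with Benjamini-Hochberg adjustment over 23 lists). The strongest were at rpl-3, rpl-12, rpl-35 and rpl-20. Chaperone genes followed with 11 of 40 (odds ratio 6.17, 3.11 to 12.22; adjusted p = 0.00018, Fisher's exact test), led by hsp-1, dnj-25, hsp-60 and cct-1. Genes of oxidative phosphorylation had 9 of 46 (odds ratio 4.00, 1.96 to 8.17; adjusted p = 0.011, Fisher's exact test), led by the cytochrome c oxidase genes cox-5A and cox-6B, then ndub-8 and cox-5B. In the single libraries, with genes holding one of the 2000 strongest regions as the bound set, the odds ratio was above 1 in 4 of 4 libraries for all 3 lists, and averaged 8.16 ± 2.07 (SD, n = 4) for ribosomal proteins, 4.61 ± 1.94 (SD, n = 4) for chaperones and 4.65 ± 1.19 (SD, n = 4) for oxidative phosphorylation. An odds ratio above 1 in 4 of 4 libraries was not particular to these lists. The lists of mitochondrial ribosomal proteins, translation factors and tRNA synthetases, proteasome, V-ATPase and cell cycle had it too. So did those of basic helix-loop-helix factors, neuronal function and microRNAs. By adjusted p (Fisher's exact test), ribosomal proteins passed in 4 of 4 libraries, chaperones in all but replicate 3 (odds ratio 2.05, adjusted p = 0.54) and oxidative phosphorylation in all but replicate 1 (adjusted p = 0.055). In the upper part of the IDR list by signal, oxidative phosphorylation did not pass, though its odds ratio was no lower (4.65, 1.9 to 11.36, adjusted p = 0.068, Fisher's exact test). When peaks were restricted to those found in all 4 libraries, the ribosomal list alone passed. Oxidative phosphorylation then had 4 of 46 genes with a peak (odds ratio 6.86, 2.57 to 18.27, adjusted p = 0.062, Fisher's exact test). Chaperones had 2 of 40 (odds ratio 4.17, 1.15 to 15.09, adjusted p = 0.72, the same exact test). The other genes include piRNA genes, which rarely had a peak. Against protein-coding genes alone, a background added after the data were seen, the odds ratios were lower and all 3 lists passed: 7.97 (4.84 to 13.12; adjusted p = 4.3e-11) for ribosomal proteins, 5.05 (2.54 to 10.03; adjusted p = 0.001) for chaperones and 3.26 (1.59 to 6.69; adjusted p = 0.04, Fisher's exact test) for oxidative phosphorylation. The control library was not used here, so recovery of highly transcribed genes was not separated from binding at these lists.

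The other 20 lists did not pass with the IDR peaks. By the same exact test, 6 of 39 mitochondrial ribosomal protein genes (adjusted p = 0.10, mrps-17 and mrpl-47 the strongest), 6 of 45 translation factor and tRNA synthetase genes (adjusted p = 0.15, eif-3.C and eef-1A.1), 4 of 17 V-ATPase genes (adjusted p = 0.094, vha-8 and vha-12), 4 of 19 cell cycle genes (adjusted p = 0.10, lin-23 and efl-1) and 3 of 21 proteasome genes (adjusted p = 0.33, pbs-2, pas-2 and rpn-3) had a peak. Transcription factor families did not pass the exact test: 2 of 14 genes of the fixed basic helix-loop-helix list (hif-1 and hlh-11; the list leaves out aha-1, which had a peak found in all 4 libraries, 128 bp from its 5′ end), 3 of 40 homeobox genes (unc-42, ceh-24 and ceh-89) and 1 of 98 nuclear hormone receptor genes (nhr-48; adjusted p = 0.10, odds ratio 0.24) had one, and none of 3 genes of the Snail, ZEB and related group did. Among tissue lists, 3 of 24 genes of neuronal function (the kinesin gene unc-104, rab-3 and unc-31), 4 of 43 neuropeptide genes (ins-39, flp-22, nlp-4 and flp-7), 2 of 37 cuticle collagen genes (col-71 and col-55) and 1 of 17 body wall muscle genes (unc-60) had a peak. No peak was found at the 6 pharyngeal, 23 epidermal, 19 intestinal and 12 germline genes that could have been called. For histones the count was 1 of 13 (his-37), and for microRNAs 0 of 2.

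**Figure D2:**
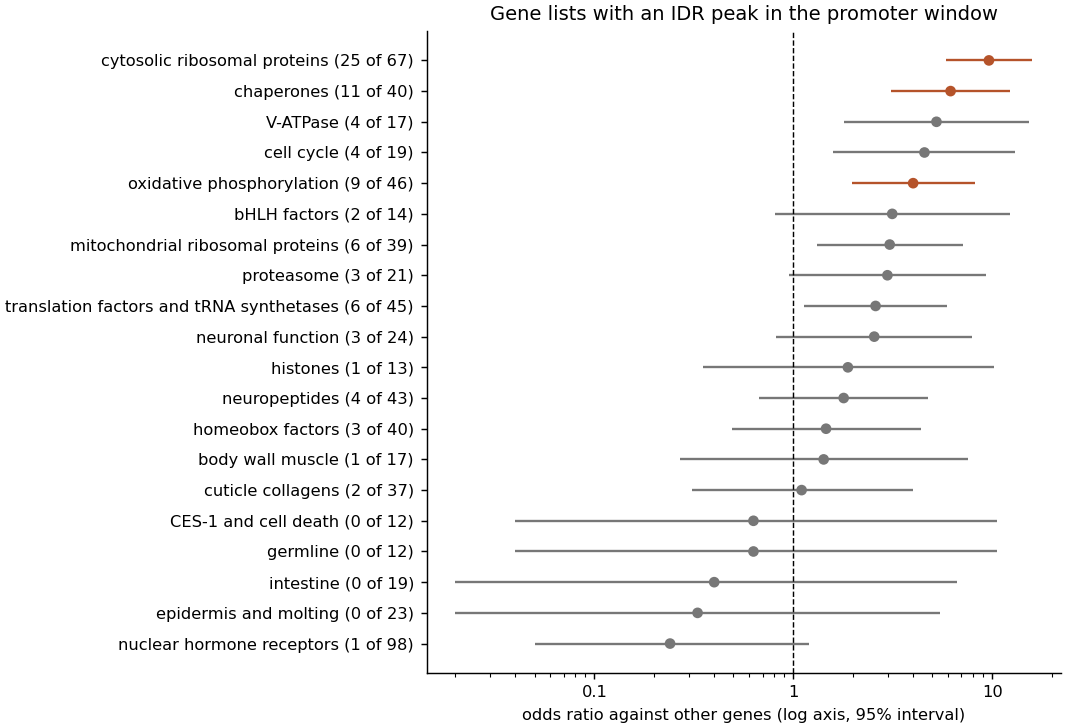
Odds ratios, on a log axis, of having an IDR peak in the promoter window for the fixed gene lists with at least 10 genes in the background, with the number of genes that had a peak and the number in the background in brackets. Points are odds ratios and lines 95% confidence intervals; coloured lists, ribosomal proteins, chaperones and oxidative phosphorylation, have an adjusted p under 0.05.

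The fixed rule named 25 protein-coding genes, those with the strongest promoter peaks found in all 4 libraries. Of these, 8 were mitochondrial, including COX3 and ND1, where the windows cover much of the compact chromosome and a peak cannot be tied to one gene. The other 17 were nuclear. After unc-42 came rpl-3, with a peak on chromosome III from 3867457 to 3867718 (pooled signal 318.3) whose summit lay between genes, 271 bp from the 5′ end; it ranked between 16 and 26 in the libraries. At cdc-48.1, which encodes an AAA-type ATPase of protein degradation, the peak on chromosome II from 10563458 to 10563676 (257.8) lay 155 bp from the 5′ end. At rpl-12 the peak on chromosome IV from 13240603 to 13240811 (227.4) was shared with the window of lin-54, and at Y17G9B.5, on chromosome IV from 4749971 to 4750159 (190.0), with that of rpl-20. At rpl-35 the peak lay on chromosome III from 7854590 to 7854795 (221.3). Peaks at the polarity kinase gene par-1 (chromosome V, 14140864 to 14141008, 187.7) and at the hypoxia-inducible factor gene hif-1 (chromosome V, 20782350 to 20782442, 159.0) lay in introns. On X, the named genes were nspc-17, apl-1, which encodes an amyloid precursor protein relative, and the insulin-like gene ins-39. Peaks at egg-5 and H41C03.3 shared their windows with the trans-splicing leader RNA genes sls-2.4 and sls-2.1. The remaining nuclear genes were C37A2.8, mrck-1, Y49F6B.2 (shared with col-71) and tasp-1. All 17 nuclear peaks ranked within the first 210 regions of every library.

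CAGGTG, the E-box bound by Snail-family proteins, was less frequent at the IDR peaks than at weaker regions. It lay within 50 bp of the summit at 10 of 1033 peaks (0.97%), against 125 of 5139 pooled regions (2.43%) matched on GC content and promoter class, an odds ratio of 0.41 (95% confidence interval 0.22 to 0.77; adjusted p = 0.022, two-sided Fisher's exact test over 10 E-boxes). It was the 1 E-box of the 10 that passed, but low odds ratios were not limited to it. Those of CAGCTG (0.59, 0.36 to 1.0), CAGATG (0.61, 0.41 to 0.92), CAACTG (0.73, 0.52 to 1.04) and CAAATG (0.76, 0.58 to 0.99) were also below 1 and did not pass. CACGTG (0.98) and CATATG (0.99) lay near 1. CAAGTG (odds ratio 1.31, adjusted p = 0.10), CAATTG (1.33, adjusted p = 0.11) and CACATG (1.3, adjusted p = 0.13) had the highest odds ratios, and none passed Fisher's exact test. The matching left out annotation class. Coding exons held 1.7% of the nuclear peak summits and 12.9% of the other pooled regions, and whether this lowers the CAGGTG share was not tested. In the single libraries, without matching on GC content or promoter class, CAGGTG lay at 1.35% ± 0.57 (SD, n = 4) of the 1000 strongest nuclear regions. It lay at 2.26% ± 0.21 (SD, n = 4) of the 10000 weakest. The odds ratio was below 1 in each library: 0.52, 0.34, 0.93 and 0.65 in replicates 1 to 4, with the interval of replicates 3 and 4 including 1. At peaks found in all 4 libraries, 2 of 282 had the motif, and the difference no longer passed (odds ratio 0.33, adjusted p = 0.25, Fisher's exact test).

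**Figure D3:**
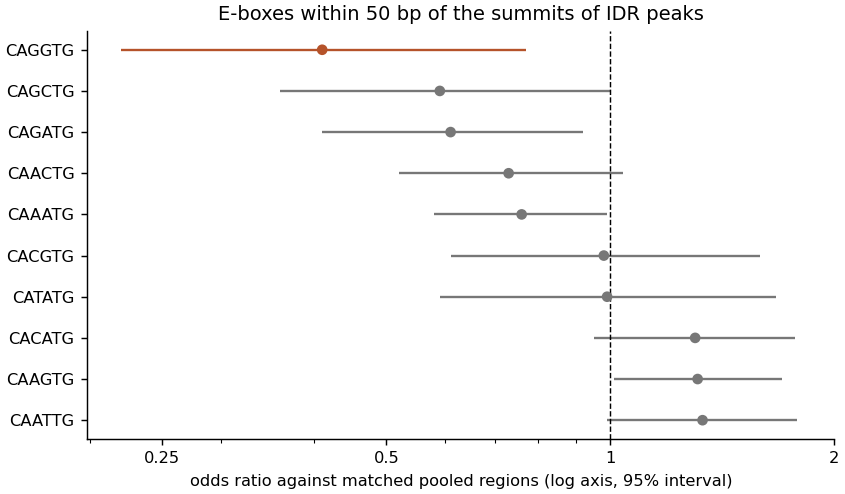
Odds ratios, on a log axis, of each of the 10 E-boxes within 50 bp of IDR peak summits against matched regions of the pooled list. Points are odds ratios and lines 95% confidence intervals; the coloured CAGGTG, at 0.41, has an adjusted p under 0.05.

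Peaks lay near 5′ ends more often than expected by chance, and mostly outside coding sequence. In the promoter window lay 603 of 1033 summits (58.4%), against 39.0% on average when summits were placed at random within their chromosomes (p = 0.001, 1-sided permutation of positions, the smallest value 1000 draws can give) and 46.4% of pooled regions without an IDR peak (odds ratio 1.62, 1.43 to 1.84; p = 4.6e-14, Fisher's exact test). In the libraries, 55.7% ± 3.59 (SD, n = 4) of the 1000 strongest nuclear regions lay there, and 42.4% ± 0.98 (SD, n = 4) of the 10000 weakest. Of the 1007 nuclear summits, 55.3% fell between genes and 29.4% in introns of protein-coding genes. Coding exons held 1.7%, against 12.9% of the other pooled regions (odds ratio 0.12, adjusted p = 7.8e-37, Fisher's exact test over 6 features), and 3′ UTRs 1.6% against 5.1% (odds ratio 0.31, adjusted p = 2.6e-08). Exons of non-coding genes held 8.9% against 3.2% (odds ratio 2.95, adjusted p = 5e-16, the same exact test). The share depends on the window: counting protein-coding genes only, it was 41.2% against 31.8% of the other pooled regions, and with 500 bp upstream and 100 bp downstream of any gene, 45.8% against 30.5%. For the peaks found in all 4 libraries the promoter share was 52.1%, and the comparison with pooled regions did not pass (odds ratio 1.26, p = 0.063, Fisher's exact test).

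The X chromosome carried the most nuclear peaks, 258 of 1033 (25%), or 14.56 per Mb, against 7.74 to 11.25 per Mb on the autosomes. Of the pooled regions, 20.6% lay on X (odds ratio 1.28, 1.11 to 1.48; adjusted p = 0.0031, Fisher's exact test over 7 chromosomes). In the libraries, the odds ratio of X among the 1000 strongest against the 10000 weakest nuclear regions averaged 1.47 ± 0.17 (SD, n = 4) and was above 1 in 4 of 4. Among the upper part of the IDR list by signal, X held 23.8% (odds ratio 1.21, 0.98 to 1.48), and the comparison did not pass (adjusted p = 0.11, Fisher's exact test). Among the nuclear peaks of that part, a restriction chosen after the data were seen, X held 25% (odds ratio 1.29, 1.05 to 1.58), with an adjusted p of 0.15 by the same exact test. The mitochondrial chromosome carried 26 IDR peaks, and 15 of the 20 strongest peaks of the list were mitochondrial. Their median pooled signal was 330.6, against 58.5 for nuclear peaks, and they covered 50.7% of the 13794 bp.

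Libraries shared part of their strongest regions. An IDR peak was counted as found in a library when its summit lay inside one of the 2000 regions of highest signal there. Replicate 1 held 816 of the 1033 peaks (79.0%), replicate 2 held 869 (84.1%), replicate 3 held 502 (48.6%) and replicate 4 held 705 (68.2%), a mean of 70.0% ± 15.7 (SD, n = 4). All 4 libraries held 282 peaks (27.3%), where random placement gave a median of 5 and at most 14 in 1000 draws. The IDR list was made from the same libraries, so these shares are not independent evidence. Without replicate 3, 475 peaks were found in all remaining libraries.

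Between pairs of libraries, 34.7% ± 8.0 (SD over 6 pairs) of the 2000 strongest regions overlapped by at least 1 bp. The highest share was 47.3% between replicates 1 and 2 and the lowest 27% between replicates 3 and 4, each a pair with the same fragmentation entry in the labels. Pairs with the same entry averaged 37.1% and pairs with different entries 33.4%; with 3 ways to split 4 libraries into pairs, no split can give a p under 0.33. In 6 of 6 measures of support, overlap, signal, locus rank and mitochondrial regions, replicates 1 and 2 both lay above replicates 3 and 4. A measure separated by this pairing cannot be separated by another, so that the other pairings separated none of these 6 follows from it and adds no evidence. Of 6 shares of the 1000 strongest regions (motifs, promoter window and X), the same pairing separated 1 and each other pairing 2. The split by fragmentation entry was thus not seen in all measures. The measures share the same lists and are not independent. The SD over 4 libraries includes the differences between these pairs. Across IDR peaks, Spearman's rho between the signals of 2 libraries averaged 0.36 ± 0.03 (SD over 6 pairs) and ran from 0.32 to 0.39; these are correlations across peaks, which are not replicates.

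**Figure D4:**
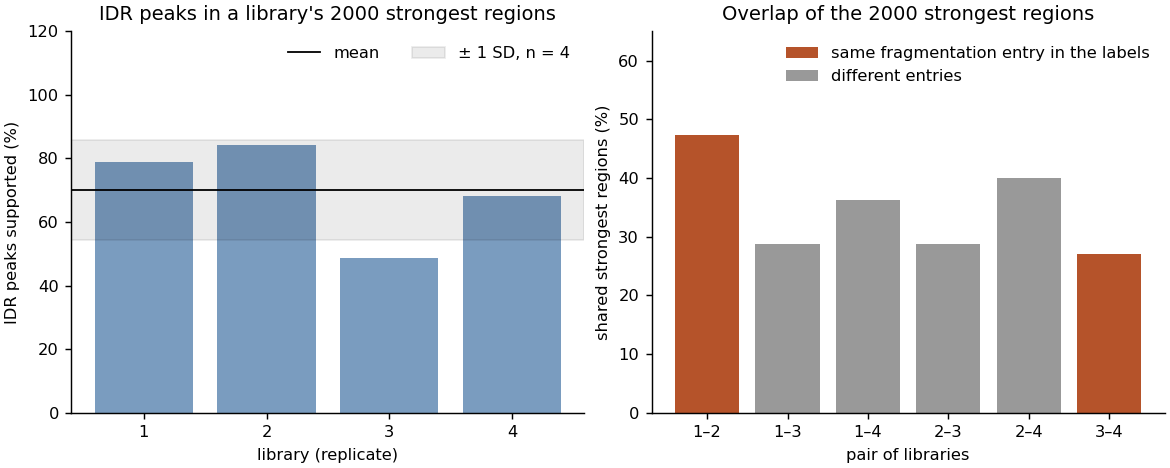
Left, the percentage of the 1033 IDR peaks with the summit in one of a library's 2000 strongest regions, one bar per replicate, with the mean (line) and ± 1 SD (band, n = 4). Right, the percentage of the 2000 strongest regions shared by each pair of libraries, coloured by the fragmentation entry in the labels; replicate 3 has the lowest bar on the left, 48.6%, and the pair of replicates 3 and 4 the lowest on the right, 27%.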

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

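Of 69 alternative settings, 48 left a result on the same side of its threshold, within its spread or, for a count, within 1.5 times the main count, and 2 changed a direction: protein-coding genes, above other genes at an odds ratio of 1.55, fell to 0.82 (adjusted p = 0.016, exact test) without piRNA genes and to 0.74 (adjusted p = 0.00016) without piRNA genes and pseudogenes, since these rarely bound genes made up much of the comparison. Restrictions to nuclear peaks and to peaks outside promoter windows, some backgrounds for X, and the settings for gene kinds and the palindrome, and protein-coding genes as the background of the lists, were chosen after seeing the data. The comparisons in the rest of this part that no longer passed used fewer peaks or a rarer motif, and whether that is the whole cause was not tested. For the promoter share the odds ratio was itself lower, 1.39 in the upper part of the list and 1.26 at peaks found in all 4 libraries, against 1.62 in the main test. The gene kinds that no longer passed, given further below, kept the same peaks and left out piRNA genes, or these and pseudogenes. CAGGTG was no longer past the threshold as ACAGGTG (0.19% of peaks), at peaks found in all 4 libraries (0.71%) or at peaks outside promoter windows (1.16%), where the adjusted p was 0.22, 0.25 and 0.16; over all its alternatives the adjusted p ran from 0.00022 to 0.25 and the odds ratio from 0.26 to 0.43. The promoter share fell to 52.1% at peaks found in all 4 libraries and did not pass (p = 0.063, Fisher's exact test), and the X share, 23.8% in the upper part of the list by signal, did not pass either (adjusted p = 0.11), nor did the 25% among the nuclear peaks of that part (adjusted p = 0.15). The number of gene lists called moved from 3 to 7 with all annotated genes as background, the 3 main lists among them. It moved to 2 in the upper part of the list by signal, where oxidative phosphorylation no longer passed. At peaks found in all 4 libraries it moved to 1, cytosolic ribosomal proteins. The odds ratio of oxidative phosphorylation was 4.65 in the upper part and 6.86 at peaks found in all 4 libraries, against 4.0 in the main test. That of chaperones was 4.17 at peaks found in all 4 libraries, against 6.17 in the main test. The mean percentile of the ces-1 window was 17.8 in 20 kb windows and 20.6 to 36.8 with 1 library left out, within 1 SD of the main value. The upper part of the list holds 517 peaks by construction. Peaks found in all libraries numbered 177 with the 1000 strongest regions, 447 with the 5000 strongest, and 325 to 475 when 1 library was left out, the highest without replicate 3. The mean correlation between libraries was 0.53 as Pearson's r of log2 signal and 0.32 for nuclear peaks alone; the cause was not tested. No paired analysis was possible because there is 1 group. Read depth is unknown, so whether replicate 3 differs through depth cannot be computed from these lists.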

Other observations

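The tests on base composition, on the motif of dosage compensation and on CAGGTG outside promoter windows were set before their results were seen; the other tests in this part were chosen after. None of 12 measures taken per library set 1 library apart by Dixon's test at its 95% level (largest ratio 0.75), a test that cannot see a split into pairs.

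Small nucleolar RNA and tRNA genes carried peaks more often than other nuclear genes, and the size of this depends on the genes they are compared with. Of 170 small nucleolar RNA genes with a region of the pooled list in the promoter window, 31 (18.2%) had an IDR peak (odds ratio 3.76, 2.54 to 5.57; adjusted p = 2.7e-08, Fisher's exact test over 10 kinds of gene), and of 386 tRNA genes, 43 (11.1%; odds ratio 2.11, 1.53 to 2.91; adjusted p = 5.9e-05). piRNA genes had few, 69 of 4861 (1.42%; odds ratio 0.18), and so did pseudogenes, 3 of 379, which lowers the share among the genes that each other kind is compared with: lincRNA genes (odds ratio 3.02, adjusted p = 0.01), other non-coding RNA genes (1.7, adjusted p = 1.3e-10) and protein-coding genes (1.55, adjusted p = 1.8e-10) were above 1 as well by the exact test, while miRNA genes did not pass (adjusted p = 0.13). With piRNA genes left out, the odds ratio was 2.79 for small nucleolar RNA genes (adjusted p = 2.6e-05, Fisher's exact test) and 1.56 for tRNA genes (adjusted p = 0.025), protein-coding genes passed in the other direction (0.82, adjusted p = 0.016), and lincRNA genes (2.24) and other non-coding RNA genes (1.17) no longer passed the exact test (adjusted p = 0.069 for both). With pseudogenes left out too, it was 2.7 (adjusted p = 7.2e-05) and 1.5, and tRNA genes did not pass (adjusted p = 0.055, exact test), while protein-coding genes stood at 0.74 (adjusted p = 0.00016). Small nucleolar RNA genes often lie in introns of other genes, so a peak near one can belong to the host. Recovery of highly transcribed genes was not separated from binding here, since the control was not used.

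Of the 20 strongest X peaks, 16 had the summit between genes, 3 in an intron and 1 in a coding exon; 4 of the 20 had it in a promoter window, and 11 had within 100 bp of the summit a match, with at most 2 mismatches, to TCGCGCAGGGAG, the 12 bp motif of X recruitment sites of the dosage compensation complex. Over all X peaks, 18 of 258 (7.0%) had it, against 19 of 4965 other pooled X regions (0.38%), an odds ratio of 19.51 (10.2 to 37.35; p = 1.3e-14, Fisher's exact test). On autosomes the values were 8 of 749 peaks and 58 of 19368 regions (odds ratio 3.78, 1.84 to 7.80). In the libraries, the motif lay within 50 bp at 1.52% ± 0.19 (SD, n = 4) of the 1000 strongest and 0.11% ± 0.03 (SD, n = 4) of the 10000 weakest nuclear regions. Examples are the X peaks from 11093968 to 11094318 (pooled signal 303.6), from 16682018 to 16682276 (259.7) and from 8036296 to 8036505 (164.4), whose nearest protein-coding gene is xol-1, at 4912 bp. Among the 100 strongest nuclear peaks, 36 were on X.

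The excess of peaks on X was weighed against base composition and against this motif. Against pooled regions matched on GC content and promoter class, the odds ratio of X stayed at 1.25 (1.07 to 1.46), so that composition is not its whole source. With every peak and region carrying the motif left out, it was 1.27 (1.09 to 1.47). Peaks with a match therefore do not account for the whole excess in number, though they are frequent among the strongest X peaks. They are 18 of 258 X peaks, so leaving them out could change the odds ratio little. Recruitment sites with weaker or more distant matches stay in the comparison, so recruitment sites as a whole are not excluded. A hypothesis is that the strongest X peaks mark recruitment sites, either through open chromatin that many immunoprecipitations recover or through an interaction of the tagged factor; a control library or another factor in the same strain background, not analysed here, would tell these apart. Recruitment sites apart, no biological explanation was tested, since the series has 1 group.

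Several 8-mers were more frequent at the peaks than at matched regions. The 8-mers of the 476 nuclear peaks on chromosomes I, III and V were compared with matched regions, and the 8 leading, mutually distinct ones were then tested on the 531 peaks on II, IV and X. The first, AATTGAAT, lay within 100 bp of 110 of these 531 summits (20.7%), against 5.55% of matched regions (odds ratio 4.45, 3.41 to 5.82; adjusted p = 1.9e-24, Fisher's exact test over 8 motifs). AATCGAAT had an odds ratio of 2.78 (1.81 to 4.28) and AATCTAAT 3.25 (1.90 to 5.57), and 6 of the 8 had an adjusted p under 0.05. The other 3 of these were rich in purines: AAAGAAGA (2.07, 1.52 to 2.82), TAGAGAGA (2.14, 1.21 to 3.77) and AGAAAAAG (1.69, 1.23 to 2.31). In the libraries AATTGAAT lay within 50 bp at 9.95% ± 2.59 (SD, n = 4) of the 1000 strongest nuclear regions and 2.48% ± 0.11 (SD, n = 4) of the 10000 weakest, with odds ratios of 4.07, 5.69, 3.00 and 4.69 in replicates 1 to 4. These library values include chromosomes I, III and V, where the 8-mer was found, and were not matched on GC content or promoter class. They show the spread between libraries and are not separate evidence. AATTGAAT, AATCGAAT and AATCTAAT are contained in forms of TAATNNNATTA, the palindrome bound by dimers of paired-like homeodomains; the purine-rich 8-mers are not. Among palindromes with 0 to 6 bases between TAAT and ATTA, a spacing of 3 was the one that passed, on all nuclear peaks (25 of 1007, 2.48%, against 0.96%; odds ratio 2.66, 1.64 to 4.32; adjusted p = 0.0015, Fisher's exact test over 7 spacings) and on the peaks of II, IV and X alone (16 of 531, 3.01%, against 1.02%; odds ratio 3.05, 1.65 to 5.66; adjusted p = 0.009, the same exact test). The palindrome was picked from the 8-mers, which match it, so this is not separate evidence. The leading unc-42 peak has an AATTGAAT match, on the reverse strand, in the bases from 9765809 to 9765869 of chromosome V, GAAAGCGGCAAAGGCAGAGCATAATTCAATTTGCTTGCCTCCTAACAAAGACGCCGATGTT; the 4 other peaks within 2 kb of unc-42 have none within 100 bp.

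CAGGTG below background and unc-42 as the leading nuclear locus were weighed together. Dilution by peaks inside promoter windows does not account for the first. At peaks outside promoter windows, CAGGTG within 100 bp was also low (odds ratio 0.42, 0.22 to 0.79). Within 50 bp, 5 of 430 such peaks had it, and the interval included 1 (0.42, 0.18 to 1.02, adjusted p = 0.16, exact test). The statement on promoter windows thus rests on the wider motif window. Active promoters away from annotated 5′ ends stay among these peaks, and dilution by them was not tested. Peaks carrying the motif at the background rate would dilute an enrichment towards an odds ratio of 1, not below it. Extra copies of the unc-42 region stay open for the second. The stretches from 5 to 20 kb on either side of the gene lay at a mean percentile of 38.9 ± 33.4 (SD, n = 4), at most 83.1 in 1 library, but the scale of the score is not stated, so an even gain in copies need not raise it, and a shorter copy would not reach these stretches. A candidate explanation that also stays open is that the material holds another tagged factor than the labelled one, such as a homeodomain protein: CAGGTG had a mean odds ratio of 0.61 over the libraries and was above 1 in none, but the TAATNNNATTA odds ratio had a lower limit above 1 in replicates 1 and 4 only (1.89, 1.24, 1.18 and 2.16 in replicates 1 to 4). Some other E-boxes also had odds ratios below 1 at the IDR peaks without passing, and some were above 1. A low odds ratio was thus not particular to the Snail-family site. Binding of CES-1 through other factors was not tested. The lists alone cannot settle which protein was precipitated.

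The mitochondrial peaks may come from the abundance of mitochondrial DNA. Regions covered 54.3% ± 10.4 (SD, n = 4) of the mitochondrial chromosome, from 45.2% to 68.5%; this meets what abundance needs, but weakly, because the bound was written after the regions had been seen and in replicates 2 to 4 the coverage is close to the summed width of the regions (7617 of 8291 bp, 6645 of 7336 bp and 6228 of 6695 bp), so that it says little beyond their number; in replicate 1 they overlap (9444 of 16337 bp). A mitochondrial region ranked first in each of the 4 libraries. The signal was uneven: the strongest mitochondrial region had 3.88 to 7.59 times the signal of the median one. Binding at mitochondrial sites is not excluded. A copy number or coverage track from the control, not used here, would be the direct test. A tagged protein in mitochondria was not tested.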
